A study of Mus musculus with 360 samples.

How the data were processed

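RNA of lung, heart, left liver lobe, kidney and ovary of female B6D2F1 mice, a first-generation cross of C57BL/6 and DBA/2 mice, was measured with the Mouse S1500+ v1.2 TempO-Seq panel. TempO-Seq counts pairs of detector oligonucleotides that are ligated on a target RNA, amplified by PCR and sequenced. Per the labels, the mice were 9 weeks old, tissues were collected on study day 5 in the order lung, heart, liver, kidney and ovary, kept in RNAlater, and extracted with QIAzol and RNeasy kits. The deposited values are counts of reads per probe, with one library per column; Bowtie 1.3.1 is named in the submitters' processing notes, and the probe manifest or genome it was run against is not stated. The table holds 3154 probes for 2756 genes, of which 4 probes had no count in any library.

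The authors' counts carry an attenuation adjustment. For 59 of the probes detected in over 100 libraries, every value was a whole multiple of a factor between 2 and 21, so for these probes the deposited value was read as the read count times that factor. The factors are not in the labels, and for other probes none could be seen. A median of 41.8% of a library's deposited counts fell on these probes. The counts were otherwise not scaled between libraries. Among 824 pairs of libraries of the same group, 0 were identical, and the smallest chi-square per degree of freedom between libraries of a pair was 7.82, with a median of 65.4. No pair was thus a copy, and each library was taken as the animal that its label numbers. The reads carry no unique molecular identifiers, so any interval derived from counts alone would cover counting error only; the intervals given here come from the spread between animals as modelled by edgeR.

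Of 360 libraries, the labels mark 326 as used in the authors' analysis, and these were analysed here. The 34 others were left out of the main comparisons and brought back in an alternative. They comprise 21 kidney libraries, of which 16 are labelled for potential tissue contamination, 3 as outliers, 1 for depth and 1 for alignment. They further comprise 11 liver libraries, of which 9 are labelled for depth and 2 as outliers, and 2 lung libraries, of which 1 is labelled as an outlier and 1 for alignment. Groups were defined by tissue, compound and concentration as labelled, which made 60 groups from 37 animals of the 1,2-dichlorobenzene series and 35 of the 1,4-dichlorobenzene series.

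Changes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on the deposited counts, with TMM scaling and filterByExpr over the 12 groups of each tissue. This left 2601 probes in liver, 2729 in kidney, 2756 in lung, 2454 in heart and 2713 in ovary. P values were adjusted by the Benjamini-Hochberg method over the probes of each contrast, and a probe passed at an adjusted p under 0.05. Tests were two-sided. Each concentration was compared with the 0 ppm animals of its own compound, so contrasts of 1 compound share their controls and their chance differences. The isomers were compared by the difference of their changes from control, at the shared concentrations of 1 and 10 ppm and at the unmatched pairs of 400 with 250 ppm and 150 with 250 ppm. The control animals of the compounds were compared with each other, and each other tissue with the liver by the difference of changes at the highest concentration. That fit scales both tissues together, so its differences need not equal those of the changes fitted per tissue. Levels are given in CPM, scaled by the effective library size, and log CPM used a prior count of 2.

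Gene lists for pathways and for cell types, 41 in all, were tested at the highest concentrations with camera of limma 3.58.1 at a preset correlation of 0.01, over lists with at least 5 probes tested. Adjustment was over 320 pairs of list and contrast, and lists were also tested with the correlation estimated from the data. Some genes belong to several lists. The groups, contrasts, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, at each highest concentration, the 8 largest rises and 8 largest falls among probes that passed with a mean of at least 20 counts, and up to 12 members of lists by smallest p. For other contrasts it takes up to 5 probes each way by adjusted p, and a fixed set of marker genes of exposure could be given in any contrast. The printed genes are examples from it, and some genes are not reported here. No fold is printed for probes with a control mean under 0.1 CPM. Where a gene has several probes, the probe with the smallest p is given. Probes of paralogs, such as those of the glutathione transferase alpha, major urinary protein, amylase and hemoglobin families, may share reads, and their values are uncertain to that extent.

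The pipeline was tested on simulated data, in which known changes were added to counts with the spread and depth of these libraries. For the highest concentration of 1,4-dichlorobenzene, edgeR recovered 56.7% of 1.5-fold changes in liver, 55.2% in kidney, 55.2% in lung, 58.2% in heart and 55.2% in ovary. For 2-fold changes the shares were 70.2%, 70.2%, 80.6%, 74.6% and 79.1% in the same order, and for 4-fold changes 78.8%, 89.4%, 89.4%, 97.0% and 95.5%. False calls numbered 9, 12, 11, 3 and 10. For differences between a tissue and the liver, the shares of 2-fold changes recovered were 52.2% for kidney, 65.7% for lung, 71.6% for heart and 55.2% for ovary.

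Animals of the compounds share numbers, and it was checked whether these pair them. The median correlation of the deviations from the group means of same-numbered animals lay between 0.042 and 0.070 over the tissues, so the numbers were not used as pairs in the main comparisons, and a fit with them as blocks is an alternative. The alternatives fixed beforehand were DESeq2 1.42.0 for the test, size factors of the RLE kind, no filter, all libraries, the attenuation factors undone, animals of the same compound only, number blocks, and leaving out each library in turn. A covariate of the Dbp level of the same animal's other tissues, and a fit without libraries whose markers of another tissue lay more than 2 log2 units above the tissue's median, were chosen after seeing the data. Gene positions are those of the annotation for the GRCm38 mouse genome; positions of the probes themselves are not stated.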

Results

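The data collected are probe counts from 5 tissues of female B6D2F1 mice of 2 exposure series, each with 5 concentrations and a 0 ppm control. The compounds, 1,2-dichlorobenzene (1,2-DCB) and 1,4-dichlorobenzene (1,4-DCB), are isomers that differ in the position of the second chlorine on the benzene ring. Heart and ovary had 10 control animals and 5 animals at each concentration, except 7 at 250 ppm 1,2-DCB. Lung had 10 controls per compound and 4 to 6 exposed animals per group. Liver had 9 controls for 1,2-DCB and 7 for 1,4-DCB, with 2 animals at 1 ppm 1,2-DCB and 4 to 6 in the other groups. Kidney had 5 controls for 1,2-DCB and 6 for 1,4-DCB, with 2 animals at 100 ppm 1,2-DCB, 3 at 30 ppm and 4 to 6 in the other groups. Deposited totals had a median of 19.4 M counts per liver library, 12.5 M in kidney, 20.1 M in lung, 12.3 M in heart and 5.93 M in ovary. The smallest was 4.34 M, in ovary, and the largest 46.5 M, in lung. With the attenuation factors undone, median counts in liver were 8.52 M in the 1,2-DCB series and 15.7 M in the 1,4-DCB series. The 10 probes with most counts took from 22% of an ovary library to 74.6% of a heart library. Log2 changes are given with their standard error, levels in CPM with their standard deviation, and n as controls and exposed animals.

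**Figure D1:**
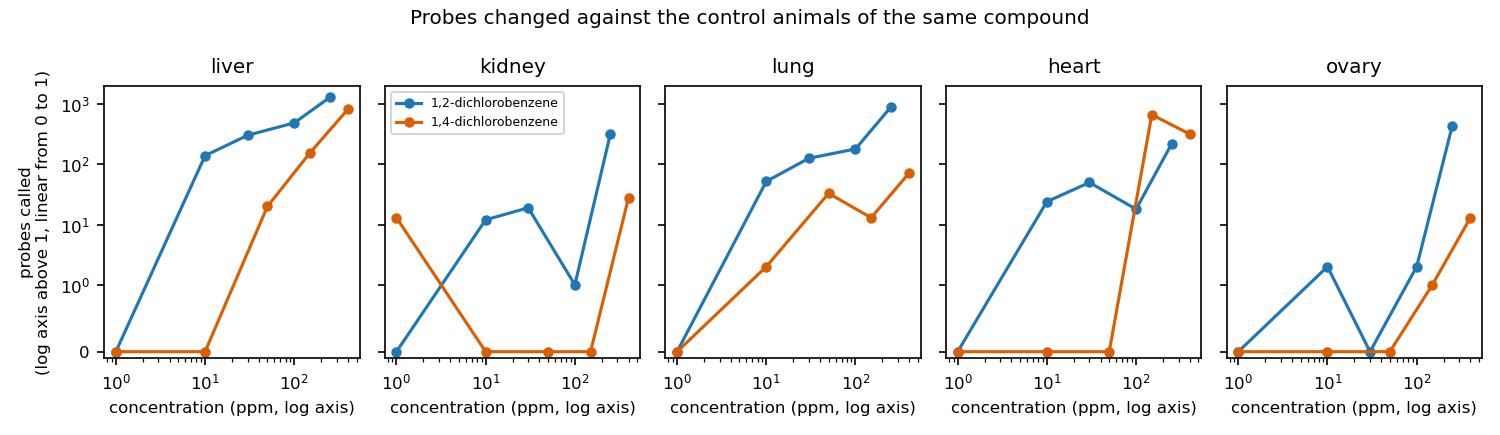
Probes with an adjusted p under 0.05 against the controls of the same compound (vertical axis, number of probes, logarithmic above a linear stretch near 0) by concentration in ppm (horizontal axis, logarithmic), per tissue and compound. The most were 1294 in liver at 250 ppm 1,2-DCB, and heart peaked at 150 ppm in the 1,4-DCB series, with 668.

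The first question was how the liver differed from control after 250 ppm 1,2-DCB. Alpha-fetoprotein (Afp), a fetal liver protein, rose by 7.94 ± 0.40 on the log2 scale, from 11.8 ± 3.52 to 2888 ± 1052 CPM (n = 9 and 6, adjusted p = 9.51e-24), and was higher in 6 of 6 exposed animals. The glutathione transferase gene Gsta1 rose by 7.22 ± 0.37, Gm3776 by 6.59 ± 0.34 and Gstm3 by 4.44 ± 0.20. The DNA replication genes Rrm2 and Mcm2 rose by 3.67 ± 0.25 and 3.06 ± 0.19. Mup19, a major urinary protein, fell by 4.96 ± 0.22 on the log2 scale, from 18464 ± 5591 to 594 ± 189 CPM. In all, 1294 of 2601 probes changed, 654 higher and 640 lower.

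By list, 52 of 57 cell cycle probes rose and 0 fell in liver at 250 ppm 1,2-DCB, as in Rrm1 with 2.24 ± 0.11 (camera, adjusted p = 1.32e-21, and adjusted p = 0.0921 with an estimated correlation). Of 24 NRF2 targets, genes of the oxidative stress response, 18 rose and 1 fell, among them Cbr3 by 3.78 ± 0.16 and Nqo1 by 2.08 ± 0.15, and this list passed with an estimated correlation (adjusted p = 2.59e-05). The list of CAR and PXR targets, genes of foreign-compound metabolism, rose with 19 of 34 probes higher and 8 lower (19 and 10 adjusted over the list alone; adjusted p = 0.00155, and adjusted p = 0.375 with an estimated correlation). Within it Cyp2b10 rose by 1.85 ± 0.22 and Gstp1 by 2.75 ± 0.18, while Cyp3a11 fell by 0.58 ± 0.11 on the log2 scale, a call that ended with all libraries included (-0.41, adjusted p = 0.246). AhR targets rose with 6 of 8 higher, among them Cyp1a1 by 2.58 ± 0.47 (adjusted p = 0.0359, and adjusted p = 0.275 with an estimated correlation). PPARA targets, genes of fatty acid oxidation, fell with 16 of 23 lower and 2 higher (adjusted p = 0.0084, and adjusted p = 0.491 with an estimated correlation). Of these, Fabp1 fell by 1.38 ± 0.12 on the log2 scale. Bile acid genes fell with 6 of 8 lower and 1 higher (adjusted p = 0.00391, and adjusted p = 0.136 with an estimated correlation). Hepatocyte markers fell with 9 of 12 lower (11 adjusted over the list alone; adjusted p = 0.00069, and adjusted p = 0.109 with an estimated correlation). Cyp2e1, one of these, fell by 2.19 ± 0.15 on the log2 scale from 33856 ± 5420 CPM. All 5 red cell probes fell, with Hba-a1 at -3.28 (adjusted p = 0.0068, and adjusted p = 0.348 with an estimated correlation). Slc1a2, a glutamate transporter, fell by 5.59 ± 0.29 on the log2 scale, and its change was -6.19 without exposed animal 506R. Afp lies on chromosome 5 from 90490737 to 90508907, and Gsta1 on chromosome 9 from 78230656 to 78242684.

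At 400 ppm 1,4-DCB the same question was asked of the liver with n = 7 and 5. Gsta1 rose by 7.38 ± 0.42 (adjusted p = 4.71e-21), from 48.6 ± 34.1 to 8034 ± 942 CPM, and was higher in 5 of 5 exposed animals. Cyp2c55 rose by 5.80 ± 0.33 and Cyp2b10, a classical target of the receptor CAR, by 4.29 ± 0.27, from 72.2 ± 19.3 to 1414 ± 197 CPM. The transporter Abcc4 rose by 4.94 ± 0.46. In all, 823 probes changed, 468 higher and 355 lower, and 514 did so with all libraries included. Cyp2c55 lies on chromosome 19 from 39007019 to 39042693 and Cyp2b10 on chromosome 7 from 25897620 to 25926624.

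Of the 34 CAR and PXR targets in liver at 400 ppm 1,4-DCB, 25 rose and 0 fell (28 higher adjusted over the list alone), among them Gstm3 by 4.35 ± 0.22 and Cyp3a11 by 0.81 ± 0.12 (adjusted p = 2.59e-26, and adjusted p = 0.000103 with an estimated correlation). NRF2 targets rose with 16 of 24 higher and 1 lower, among them Cbr3 by 4.47 ± 0.19 (adjusted p = 3.55e-08 with an estimated correlation). The fatty acid synthesis list rose with 6 of 8 higher (7 adjusted over the list alone; adjusted p = 0.0265 with an estimated correlation). Of 57 cell cycle probes, 51 rose and 1 fell, as in Rrm2 with 3.21 ± 0.27, Mcm2 with 2.10 ± 0.20 and Rrm1 with 1.54 ± 0.13 (adjusted p = 8.2e-22, and adjusted p = 0.0787 with an estimated correlation). Cholesterol synthesis genes rose with 9 of 16 higher (11 adjusted over the list alone; adjusted p = 0.00469, and adjusted p = 0.489 with an estimated correlation). Interferon response genes fell with 10 of 17 lower (12 adjusted over the list alone; adjusted p = 0.0084, and adjusted p = 0.561 with an estimated correlation). Inflammation genes fell with 9 of 26 lower and 1 higher (adjusted p = 0.0482, and adjusted p = 0.663 with an estimated correlation). The neutrophil gene S100a8 was the member that rose, by 4.80 ± 0.58, and Nfkbia fell by 0.75 ± 0.11 on the log2 scale. The lung xenobiotic list rose in liver with 5 of 10 higher (adjusted p = 0.00622, and adjusted p = 0.255 with an estimated correlation). Outside these lists, Lrg1 fell by 1.92 ± 0.22 and Slc1a2 fell by 1.86 ± 0.24 on the log2 scale. The fatty acid transporter Cd36 rose by 1.31 ± 0.20, Acaa1a by 0.68 ± 0.12, and Cyp2e1 fell by 1.05 ± 0.16 on the log2 scale.

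**Figure D2:**
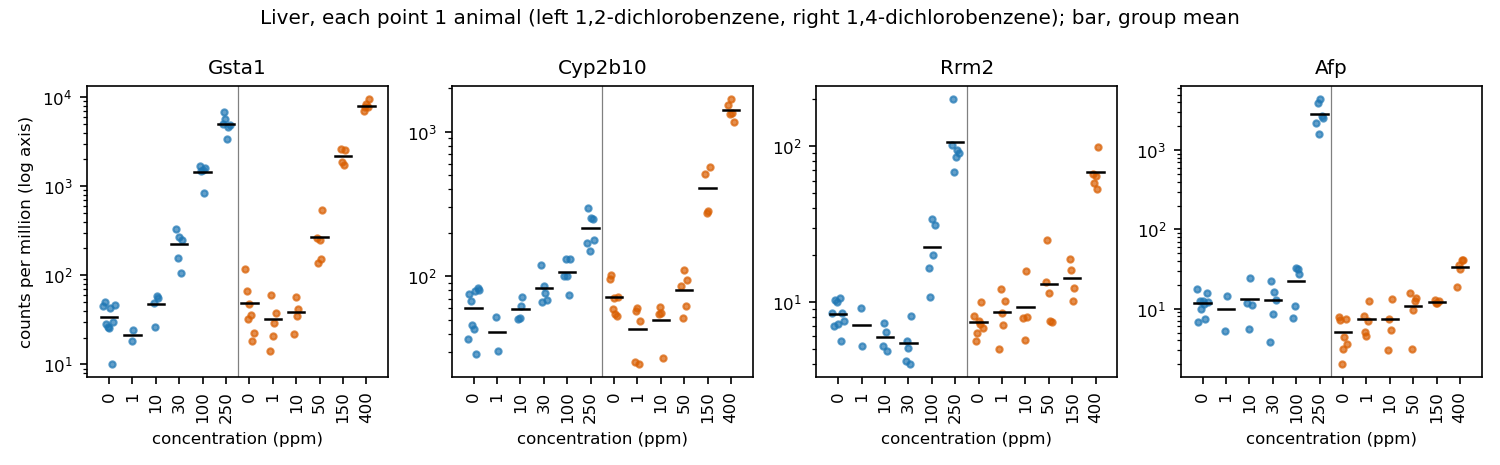
Level of Gsta1, Cyp2b10, Rrm2 and Afp in liver (vertical axis, CPM, logarithmic) by compound and concentration in ppm (horizontal axis), with a point per animal and a bar at each group mean. Afp rose at 250 ppm 1,2-DCB, from 11.8 to 2888 CPM on average, and Cyp2b10 reached 1414 CPM at 400 ppm 1,4-DCB.

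Lower concentrations were compared with the same controls to find where changes began in liver. At 10 ppm 1,2-DCB, Por, the reductase that serves cytochromes P450, rose by 1.04 ± 0.13 (n = 9 and 4, adjusted p = 1.42e-07), and Arsa by 1.61 ± 0.22. The clock gene Hlf rose by 2.05 ± 0.35, a call that ended with the Dbp covariate (0.73, adjusted p = 0.359). Cdkn1a fell by 4.22 ± 0.52 on the log2 scale, or -4.85 without animal 202, and Net1 fell by 0.86 ± 0.12. Of the probes that changed, 69 were higher and 70 lower; the count was 26 with all libraries, 81 with animals of the same compound only, 54 with the Dbp covariate and 68 without animal 201. At 30 ppm, 304 changed, 52.3% of them higher; these were 11.7% of the probes tested, against 4.2% with all libraries and 6.8% with the Dbp covariate. Gsta1 rose by 2.72 ± 0.32 and Cyp2a5 by 2.09 ± 0.29, Cdkn1a fell by 3.93 ± 0.46 and Ifi44 fell by 1.32 ± 0.21 on the log2 scale. Of the interferon genes 12 fell and 0 rose at this concentration, and 9 inflammation genes fell. At 100 ppm, 488 changed, 313 higher and 175 lower, and 238 changed with all libraries. With the attenuation factors undone, 51.6% of the called probes were higher, against 64.1% before. Gsta1 rose by 5.40 ± 0.35, Gstm3 by 2.23 ± 0.19 and Lgals1 by 1.83 ± 0.14, and Mup19 fell by 1.82 ± 0.20 on the log2 scale. Cell cycle genes higher numbered 1 at 10 ppm, 1 at 30 ppm and 44 at 100 ppm. At 1 ppm edgeR called 0 probes in 2 animals, with 54 at an unadjusted p under 0.05 and 0 by DESeq2, but 301 with all libraries.

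In the liver of the 1,4-DCB series, edgeR called 0 probes at 1 ppm and at 10 ppm, with 5.42% and 2.92% of probes at an unadjusted p under 0.05 and 0 by DESeq2 at each. At 150 ppm 5.96% of probes changed, 85.2% of them higher, and 3.58% did without animal 401. Gsta1 rose by 5.50 ± 0.40 (n = 7 and 4), Cyp2c55 by 4.26 ± 0.32, Gstm3 by 2.62 ± 0.21 and the carboxylesterase Ces2c by 2.12 ± 0.16. CAR and PXR targets higher numbered 18 at 150 ppm and 5 at 50 ppm, and NRF2 targets higher 13 and 4. At 50 ppm 20 probes changed, 19 higher and 1 lower, among them Gsta1 with 2.47 ± 0.35 (adjusted p = 5.18e-06) and Ces2c with 1.04 ± 0.15. Of the cell cycle genes, 5 rose at 50 ppm (31 adjusted over the list alone), but without animal 303 only 3 probes passed in all. With all libraries, Gsta1 at 50 ppm turned to -0.04 and Ces2c was 0.82 (adjusted p = 0.137). The 50 ppm count was 2 with all libraries, 6 with animals of the same compound only, 41 by DESeq2 and 64 with the Dbp covariate. It ranged from 3 to 57 when 1 library was left out.

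In kidney, 250 ppm 1,2-DCB raised the cholesterol synthesis list most evenly, with 13 of 16 probes higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 1.33e-17, and adjusted p = 0.00314 with an estimated correlation). Insig1, which restrains sterol synthesis, rose by 1.92 ± 0.18, from 113.8 ± 19.4 to 431 ± 105 CPM (n = 5 and 6, adjusted p = 5.41e-11, higher in 6 of 6). Acat2 rose by 0.75 ± 0.10. Gsta1 rose by 2.38 ± 0.26, while Slc22a7, an organic anion transporter, fell by 1.70 ± 0.17 on the log2 scale. In all, 320 of 2729 probes changed, 57.8% of them higher, and 180 did with the Dbp covariate. Insig1 lies on chromosome 5 from 28071363 to 28078662.

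NRF2 targets rose in kidney at 250 ppm 1,2-DCB with 8 of 24 higher and 2 lower, among them Cbr3 by 1.29 ± 0.14 (9 and 2 adjusted over the list alone; adjusted p = 0.0157 with an estimated correlation). All 5 red cell probes fell (adjusted p = 0.0113 with an estimated correlation), with Hba-a2 at -2.25 ± 0.35, or -2.84 without animal 508. PPARA targets rose with 9 of 21 higher and 2 lower, among them Cyp4a14 by 1.85 ± 0.21 (adjusted p = 1.19e-07, and adjusted p = 0.103 with an estimated correlation). CAR and PXR targets rose with 10 of 30 higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 7.75e-06, and adjusted p = 0.0737 with an estimated correlation). Clock genes rose with 3 of 6 higher and 1 lower (adjusted p = 0.00936, and adjusted p = 0.0551 with an estimated correlation). Dbp, a clock output gene, rose by 2.12 ± 0.45, a call that ended with the Dbp covariate (0.23, adjusted p = 0.694). Lists that fell were interferon genes with 3 of 17 lower (adjusted p = 0.000181, and adjusted p = 0.346 with an estimated correlation), heat shock genes with 5 of 18 lower (8 adjusted over the list alone; adjusted p = 0.00805, and adjusted p = 0.443 with an estimated correlation) and p53 targets with 3 of 22 lower (5 adjusted over the list alone; adjusted p = 0.0359, and adjusted p = 0.136 with an estimated correlation). Immediate early genes fell with 1 of 16 lower (adjusted p = 0.0231, and adjusted p = 0.496 with an estimated correlation). Mitochondrial genes rose with 4 of 13 higher (adjusted p = 0.00155, and adjusted p = 0.432 with an estimated correlation) and the lung xenobiotic list with 3 of 9 (adjusted p = 0.0208, and adjusted p = 0.215 with an estimated correlation). Hepatocyte markers also rose with 2 of 11 higher (5 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.443 with an estimated correlation). Libraries that may carry liver transcripts from another library, described below, were spread unevenly over the groups compared here.

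At 400 ppm 1,4-DCB, 28 kidney probes changed, 17 higher and 11 lower (n = 6 and 5). Gsta1 rose by 1.46 ± 0.23, from 16.1 ± 6.34 to 44.1 ± 7.39 CPM (adjusted p = 0.000214, higher in 5 of 5), and Htra1 fell by 0.45 ± 0.07 on the log2 scale. Fabp1 rose by 0.68 ± 0.12, a call that ended with all libraries (0.62, adjusted p = 0.86). Cyp2a5 and Cyp4a14 rose by 1.11 ± 0.20 and 1.00 ± 0.20, calls that ended with the Dbp covariate (0.60, adjusted p = 0.173, and 0.87, adjusted p = 0.113). CAR and PXR targets rose with 5 of 30 higher (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.00544 with an estimated correlation). Clock genes rose with 2 of 6 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.000897 with an estimated correlation), and the lung xenobiotic list with 1 of 9 higher (5 adjusted over the list alone; adjusted p = 0.0165 with an estimated correlation). NRF2 targets rose with 4 higher (5 adjusted over the list alone; adjusted p = 0.00457, and adjusted p = 0.103 with an estimated correlation) and PPARA targets with 2 higher (4 adjusted over the list alone; adjusted p = 0.00236, and adjusted p = 0.42 with an estimated correlation). The mitochondrial and red cell lists passed with 0 members past the test by edgeR (adjusted p = 0.456 and adjusted p = 0.525 with an estimated correlation). The count of 28 was 17 without animal 503, 14 without animal 504 and 6 with the Dbp covariate.

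At lower concentrations the kidney count depended on the libraries used. Htra1, a secreted protease, fell by 0.47 ± 0.08 at 10 ppm, fell by 0.68 ± 0.08 at 30 ppm (n = 5 and 3, adjusted p = 1.11e-06) and fell by 0.60 ± 0.10 on the log2 scale at 100 ppm 1,2-DCB, where it was the only call in 2 animals. Without animal 404 its adjusted p at 100 ppm was 0.102 and without animal 405 it was 0.0526, so 0 probes passed edgeR in either case. At 30 ppm Gsta1 rose by 1.60 ± 0.28 and Slc51a by 1.13 ± 0.20, the latter ended by the Dbp covariate (0.73, adjusted p = 0.289). At 10 ppm Hlf and Slc51a rose by 0.98 ± 0.17 and 0.98 ± 0.18. With the covariate Htra1 at 10 ppm was -0.28 (adjusted p = 0.305), Hlf 0.34 (adjusted p = 0.762) and Slc51a 0.59 (adjusted p = 0.506). The counts were 12 probes at 10 ppm, 7 higher and 5 lower, and 19 at 30 ppm, 10 higher and 9 lower. When 1 library was left out, the 10 ppm count ranged from 5 to 11 and the 30 ppm count from 8 to 19. With all libraries it was 279 at 30 ppm and 234 at 100 ppm, against 19 and 1. With animals of the same compound only it was 23 at 10 ppm and 48 at 30 ppm, by DESeq2 23 and 38, and with the Dbp covariate 6 at 10 ppm and 10 at 100 ppm.

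At 1 ppm 1,4-DCB, 13 kidney probes passed, 12 higher and 1 lower, among them Gclc with 1.12 ± 0.17 (n = 6 and 4, adjusted p = 8.32e-05) and Gbp3 with 0.83 ± 0.15, the latter ended by all libraries (0.66, adjusted p = 0.157). That count was 1 with all libraries, 48 by DESeq2 and from 2 to 57 when 1 library was left out. EdgeR called 0 probes at 1 ppm 1,2-DCB (169 at an unadjusted p under 0.05, DESeq2 0) and 0 at 10, 50 and 150 ppm 1,4-DCB (178, 193 and 282, DESeq2 2, 7 and 3). The counts at 50 and 150 ppm were up to 2 when 1 library was left out.

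In lung, 250 ppm 1,2-DCB raised genes of the oxidative stress response. Nqo1, a quinone reductase, rose by 2.88 ± 0.13, from 16.9 ± 2.27 to 124.15 ± 39.4 CPM (n = 10 and 6, adjusted p = 5.86e-28, higher in 6 of 6), and Gsta1 by 5.35 ± 0.24. The cystine transporter Slc7a11 rose by 3.02 ± 0.22, Cbr3 by 1.74 ± 0.11 and the carboxylesterase Ces1g by 3.40 ± 0.24. Il6, an inflammatory cytokine, rose by 2.46 ± 0.34. In all, 898 of 2756 probes changed, 484 higher and 414 lower. Nqo1 lies on chromosome 8 from 107388225 to 107403206 and Ces1g on the same chromosome from 93302369 to 93337308.

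Of 24 NRF2 targets in lung at 250 ppm 1,2-DCB, 20 rose and 0 fell (adjusted p = 1.44e-36, and adjusted p = 3e-08 with an estimated correlation). Of 58 cell cycle probes, 48 rose and 0 fell, among them Dtl by 2.40 ± 0.20 and Gins2 by 1.78 ± 0.15 (50 higher and 1 lower adjusted over the list alone; adjusted p = 1.43e-22, and adjusted p = 0.0787 with an estimated correlation). CAR and PXR targets rose with 10 of 24 higher and 3 lower, among them Gstp1 by 1.00 ± 0.10 (adjusted p = 0.00127, and adjusted p = 0.284 with an estimated correlation). AhR targets rose with 4 of 9 higher and 2 lower (adjusted p = 0.0124, and adjusted p = 0.217 with an estimated correlation), and markers of ciliated cells with 4 of 5 higher (adjusted p = 0.00189, and adjusted p = 0.131 with an estimated correlation). Interferon genes fell with 7 of 17 lower (adjusted p = 0.0498, and adjusted p = 0.496 with an estimated correlation), and hypoxia genes with 3 of 7 lower (adjusted p = 0.0249, and adjusted p = 0.106 with an estimated correlation). All 6 red cell probes fell (adjusted p = 0.116 with an estimated correlation), with Hba-a2 at -2.38 ± 0.36, or -2.99 without animal 508.

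In lung 72 probes changed at 400 ppm 1,4-DCB, 44 higher and 28 lower (n = 10 and 5). Cyp1a1, a classical target of the receptor AhR, fell by 2.75 ± 0.32 on the log2 scale, from 16.5 ± 3.64 to 2.46 ± 1.22 CPM (adjusted p = 5.73e-09, lower in 5 of 5). Ces1g rose by 2.42 ± 0.24, Slc7a11 by 1.26 ± 0.23, Nqo1 by 1.03 ± 0.14 and Gsta2 by 1.02 ± 0.18. The clock genes Hlf and Dbp rose by 1.47 ± 0.25 and 1.97 ± 0.42, or 0.69 and 0.53 with the Dbp covariate, which ended the Dbp call (adjusted p = 0.0885). Adm fell by 1.50 ± 0.24 on the log2 scale, or -0.77 with the covariate, and Lox fell by 0.89 ± 0.16. NRF2 targets rose with 6 of 24 higher (11 adjusted over the list alone; adjusted p = 0.0017 with an estimated correlation) and clock genes with 4 higher (5 and 1 lower adjusted over the list alone; adjusted p = 5.16e-05 with an estimated correlation). Targets of CAR and PXR rose with 2 higher (adjusted p = 0.000837, and adjusted p = 0.257 with an estimated correlation) and cell cycle genes with 3 higher (adjusted p = 0.000391, and adjusted p = 0.589 with an estimated correlation). The p53 list fell with 1 of 22 lower (adjusted p = 0.0146, and adjusted p = 0.116 with an estimated correlation) and the heat shock list passed with 0 of 18 past the test by edgeR (adjusted p = 0.00457, and adjusted p = 0.432 with an estimated correlation). The count of 72 was 42 without animal 505, 46 without animal 503 and 45 with all libraries. Cyp1a1 lies on chromosome 9 from 57687928 to 57703824.

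Lower concentrations moved Ces1g and Nqo1 in lung at several steps. Under 1,2-DCB, Ces1g rose by 1.77 at 10 ppm, 2.34 at 30 ppm and 2.95 at 100 ppm, and Nqo1 by 0.93, 1.54 and 1.97 (n = 10 and 5 each). NRF2 targets higher numbered 2, 7 and 12 at these concentrations, and CAR and PXR targets 4, 8 and 9. Vcam1 fell, with -0.48, -0.53 and -0.50, and so did Cdkn1a, with -1.0, -1.16 and -1.08. With the Dbp covariate the 10 ppm calls ended for Vcam1 (-0.28, adjusted p = 0.122), Cdkn1a (-0.76, adjusted p = 0.0723) and Hlf, which had risen by 1.68 (0.51, adjusted p = 0.231). The probes that changed were 26 higher and 26 lower at 10 ppm, 63 and 63 at 30 ppm, and 103 and 77 at 100 ppm. The 10 ppm count ranged from 23 to 60 when 1 library was left out, and the 100 ppm count was 104 without animal 404. With the Dbp covariate it was 23 at 10 ppm and 73 at 30 ppm. At 1 ppm edgeR called 0, with 406 at an unadjusted p under 0.05, 24 by DESeq2 and 541 with all libraries; it called up to 3.84% of probes when 1 library was left out.

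Under 1,4-DCB, Ces1g in lung rose by 1.77 at 10 ppm, 2.22 at 50 ppm and 2.32 at 150 ppm, and Nqo1 by 0.85 at 50 ppm and 1.23 at 150 ppm (n = 10 and 5 each). Cell cycle genes rose with 14 higher at 50 ppm (26 adjusted over the list alone) and 2 at 150 ppm (3 adjusted over the list alone), as in Dtl with 1.42 ± 0.21 and Cdc20 with 1.03 ± 0.18 at 50 ppm. Ugt1a6a rose by 0.80 ± 0.12 at 150 ppm. All 33 calls at 50 ppm and all 13 at 150 ppm were higher, and 2 probes passed at 10 ppm. The 50 ppm count was 15 with all libraries, 60 with animals of the same compound only and 12 to 38 when 1 library was left out. The 10 ppm count was 1 or 2 when 1 library was left out. EdgeR called 0 at 1 ppm, with 84 at an unadjusted p under 0.05 and 1 by DESeq2; 1 was called without control 1, 2 or 7.

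In heart, 250 ppm 1,2-DCB raised the monocyte chemokines Ccl2 and Ccl7, by 2.24 ± 0.20 and 1.78 ± 0.25 (n = 10 and 7, adjusted p = 5e-13 for Ccl2, higher in 7 of 7). The antigen presentation genes H2-aa and Cd74 fell by 2.21 ± 0.29 and fell by 2.02 ± 0.26 on the log2 scale. Dbp rose by 2.17 ± 0.32, or 0.90 with the Dbp covariate, Bhlhe40 by 0.80 ± 0.11 and the metallothionein Mt1 by 0.59 ± 0.08. Spp1 rose by 2.17 ± 0.53, and Prc1, a cytokinesis gene, fell by 2.06 ± 0.35 on the log2 scale. In all, 218 of 2454 probes changed, 45.9% of them higher. Clock genes rose with 4 higher and 1 lower (adjusted p = 0.00259 with an estimated correlation). Of 6 red cell probes 5 fell, as in Hba-a2 with -2.23 ± 0.42 (6 adjusted over the list alone; adjusted p = 2.44e-09, and adjusted p = 0.0555 with an estimated correlation). Interferon genes fell with 3 lower (adjusted p = 0.000337, and adjusted p = 0.405 with an estimated correlation), and cell cycle genes with 8 of 48 lower (12 and 1 higher adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.375 with an estimated correlation). NRF2 targets rose with 3 of 23 higher (adjusted p = 0.0195, and adjusted p = 0.131 with an estimated correlation). Inflammation genes rose with 2 of 23 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.224 with an estimated correlation), and the kidney injury list with 1 of 12 higher (4 adjusted over the list alone; adjusted p = 0.00201, and adjusted p = 0.456 with an estimated correlation). Ccl2 lies on chromosome 11 from 82035571 to 82037453 and Dbp on chromosome 7 from 45705088 to 45710203.

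At 400 ppm 1,4-DCB, 318 heart probes changed, 217 higher and 101 lower (n = 10 and 5). Vcam1 rose by 1.10 ± 0.21 (adjusted p = 0.000342), Ephx1 by 0.92 ± 0.15 and the keratin Krt18 by 2.04 ± 0.43, while Lcn2 fell by 1.14 ± 0.26 and Col4a1 fell by 0.60 ± 0.12 on the log2 scale. The lung club cell gene Cyp2f2 rose by 6.91 ± 1.09, Hp of the inflammation list by 5.21 ± 1.28 and Acly by 3.02 ± 0.62. These values rested on animal 501, where Cyp2f2 stood at 765 CPM; without it Cyp2f2 was 0.10 (adjusted p = 0.968), Hp 3.06 (adjusted p = 0.146) and Acly 0.86 (adjusted p = 0.43). The count was 87 without animal 501, 120 without animal 503, 6.03% of probes without libraries with another tissue's markers and 480 with the Dbp covariate. Clock genes rose with 4 higher and 1 lower (adjusted p = 0.0133 with an estimated correlation). The kidney injury list, of which Krt18 and Vcam1 are members, rose with 9 of 12 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 9.58e-06, and adjusted p = 0.276 with an estimated correlation), and inflammation genes with 8 higher and 1 lower (adjusted p = 0.0106, and adjusted p = 0.352 with an estimated correlation). Fatty acid synthesis genes rose with 6 of 8 higher (adjusted p = 0.0484, and adjusted p = 0.592 with an estimated correlation), and the lung xenobiotic list, which holds Cyp2f2, with 4 of 8 higher (6 adjusted over the list alone; adjusted p = 0.0276, and adjusted p = 0.442 with an estimated correlation). Mitochondrial genes fell with 1 of 13 lower (adjusted p = 0.00203, and adjusted p = 0.525 with an estimated correlation), cardiac contraction genes with 1 of 10 (adjusted p = 0.00622, and adjusted p = 0.525 with an estimated correlation) and cardiomyocyte markers with 1 of 7 (2 adjusted over the list alone; adjusted p = 0.00478, and adjusted p = 0.461 with an estimated correlation). The p53 list fell with 1 of 19 higher and 2 lower (adjusted p = 0.0487, and adjusted p = 0.103 with an estimated correlation).

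**Figure D3:**
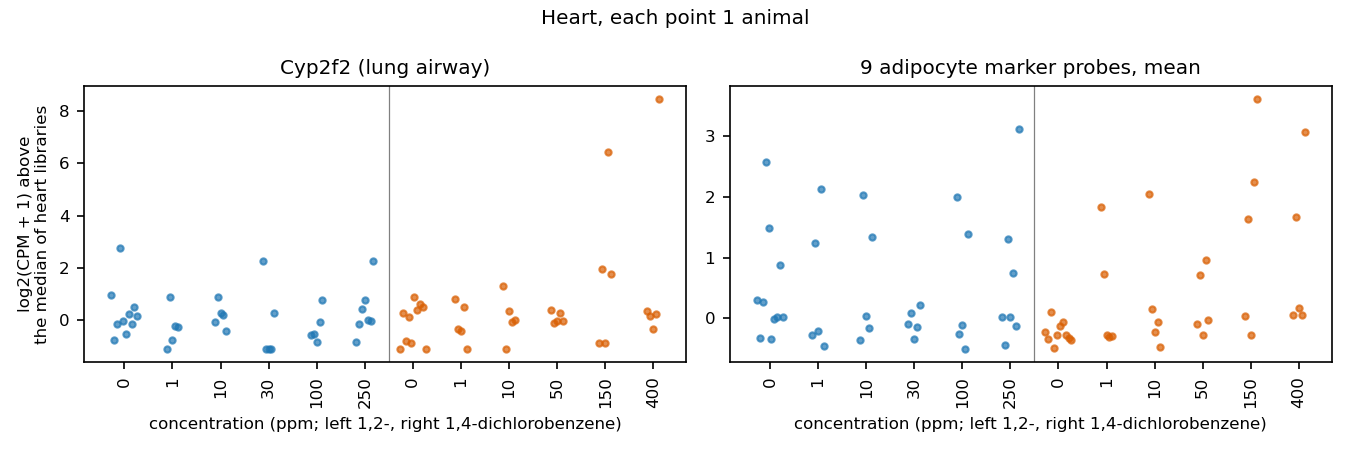
Cyp2f2, a lung gene (left), and the mean of 9 adipocyte probes (right) in each heart library, as log2 of CPM plus 1 above the median of the heart libraries (vertical axis), by compound and concentration in ppm (horizontal axis), with a point per animal. Animal 501 at 400 ppm 1,4-DCB is the highest in Cyp2f2, and animal 405 at 150 ppm in the adipocyte probes.

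At 150 ppm 1,4-DCB, 668 heart probes changed, 375 higher and 293 lower (n = 10 and 5). The muscle calcium pump gene Atp2a1 rose by 3.26 ± 0.57 and S100a4 by 1.2 ± 0.23, and Bcl2l13 fell by 0.46 ± 0.08 on the log2 scale. Extracellular matrix genes rose with 12 higher and 0 lower, mitochondrial genes fell with 10 lower and 0 higher, and 7 of 10 cardiac contraction genes were lower. Adipocyte markers lay 3.61 log2 units above the heart median in animal 405, and the lung marker 6.44 above in animal 403. Without animal 405 the count was 45, and 8 without libraries with another tissue's markers. At 1, 10 and 50 ppm edgeR called 0 probes, with 5.58%, 10.1% and 6.97% at an unadjusted p under 0.05 and 0 by DESeq2 each; without animal 204 the 10 ppm count was 1.

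Clock genes also changed in heart at lower concentrations of 1,2-DCB, with 4 higher and 1 lower at each of 10, 30 and 100 ppm. Dbp rose by 2.31 ± 0.34 at 10 ppm, 2.29 at 30 ppm and 1.94 at 100 ppm (n = 10 and 5 each), Bhlhe40 by 0.88 ± 0.13, 0.78 and 0.74, and Nfil3 fell, with -1.06 ± 0.17, -0.83 and -0.92. Cdkn1a fell, with -1.64 ± 0.27 at 10 ppm and -1.89 at 30 ppm. With the Dbp covariate the 10 ppm values were 0.60 for Dbp (adjusted p = 0.103), -0.49 for Nfil3 (adjusted p = 0.22) and -0.76 for Cdkn1a (adjusted p = 0.219). The 30 ppm values were 0.57 for Dbp (adjusted p = 0.0788), 0.53 for Bhlhe40 (adjusted p = 0.0785) and -0.26 for Nfil3 (adjusted p = 0.721), and Nfil3 at 100 ppm was -0.52 (adjusted p = 0.0732). The probes that changed were 24 at 10 ppm (9 higher, 15 lower), 50 at 30 ppm (13 and 37) and 18 at 100 ppm (7 and 11). When 1 library was left out, these counts ranged from 12 to 32, 24 to 61 and 7 to 21, and the 30 ppm count was 7 with the covariate. At 1 ppm edgeR called 0, with 102 at an unadjusted p under 0.05 and 0 by DESeq2.

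**Figure D4:**
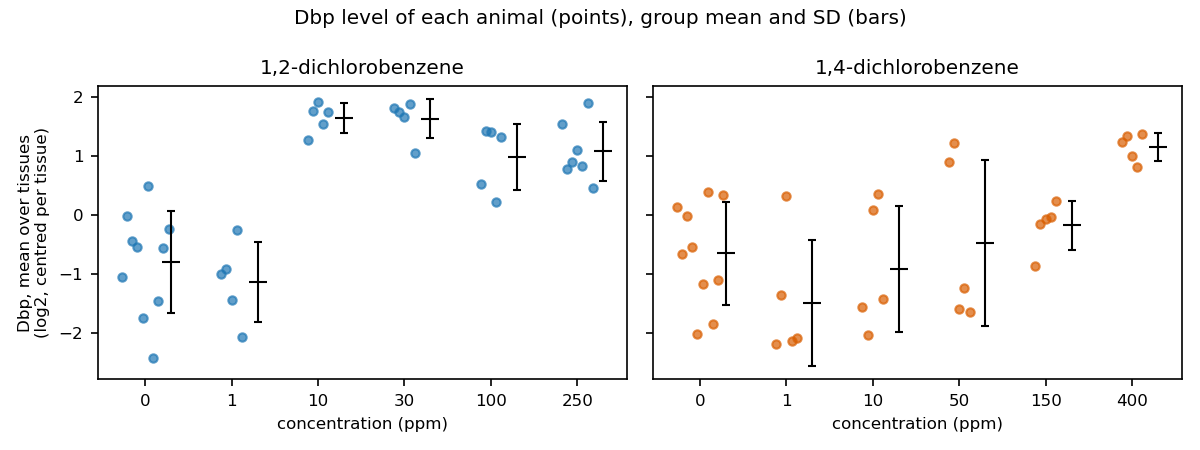
Dbp level of each animal, averaged over its tissues as log2 deviations (vertical axis), by compound and concentration in ppm (horizontal axis), with a point per animal and the group mean and standard deviation. The mean was 1.64 at 10 ppm 1,2-DCB and -0.80 in its controls, and 1.15 at 400 ppm 1,4-DCB against -0.65 in its controls.

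In ovary, 250 ppm 1,2-DCB raised the macrophage genes Chil3 and Mmp12 by 2.86 ± 0.57 and 1.78 ± 0.31, the latter from 25 ± 19.2 to 86.3 ± 44.4 CPM (n = 10 and 7, adjusted p = 0.000122, higher in 7 of 7). Ccl2 rose by 1.86 ± 0.33, Cyp2a5 by 2.20 ± 0.44 and Gsta3 by 1.39 ± 0.26. Mup19 fell by 3.67 ± 0.67 and Hba-a1 fell by 2.76 ± 0.45 on the log2 scale. Without control 4, whose hepatocyte markers lay 2.43 log2 units above the ovary median, Chil3 was 3.81 and Mup19 -3.00, without control 7, where they lay 2.15 above, Mup19 was -3.50, and without all libraries with another tissue's markers -2.56, and without animal 508 Hba-a1 was -3.71. In all, 432 of 2713 probes changed, 223 higher and 209 lower, and 221 did with the Dbp covariate. Of 57 cell cycle probes 22 rose and 0 fell, among them Hmmr by 0.65 ± 0.13, Cenpe by 0.63 ± 0.13 and Melk by 0.63 ± 0.13 (31 adjusted over the list alone; adjusted p = 7.76e-15, and adjusted p = 0.275 with an estimated correlation). Extracellular matrix genes fell with 8 of 21 lower (9 adjusted over the list alone; adjusted p = 0.000439, and adjusted p = 0.456 with an estimated correlation), cholesterol synthesis genes with 4 of 16 (8 adjusted over the list alone; adjusted p = 0.00296, and adjusted p = 0.556 with an estimated correlation) and ER stress genes with 5 of 18 (8 adjusted over the list alone; adjusted p = 0.00576, and adjusted p = 0.379 with an estimated correlation). Oocyte markers rose with 3 of 7 higher (adjusted p = 0.00725, and adjusted p = 0.343 with an estimated correlation), macrophage markers with 2 of 5 (adjusted p = 0.0219, and adjusted p = 0.379 with an estimated correlation) and adipocyte markers with 3 of 9 (6 adjusted over the list alone; adjusted p = 0.000323, and adjusted p = 0.38 with an estimated correlation). The lung xenobiotic list rose with 3 of 7 higher and 1 lower (adjusted p = 0.0299, and adjusted p = 0.379 with an estimated correlation), and endothelium markers fell with 2 of 5 lower (adjusted p = 0.0472, and adjusted p = 0.442 with an estimated correlation).

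In ovary 13 probes changed at 400 ppm 1,4-DCB, 10 higher and 3 lower (n = 10 and 5). Dbp rose by 1.11 ± 0.22 (adjusted p = 0.00208), ended by the covariate (0.48, adjusted p = 0.255). The pancreas gene Ctrb1 rose by 3.70 ± 0.68 and the intestinal gene Fabp2 by 3.60 ± 0.57; without animal 505, whose pancreas markers lay 2.59 log2 units above the ovary median, Ctrb1 was 0.44 (adjusted p = 0.947), and without animal 504 Fabp2 was 0.46 (adjusted p = 0.93). The count was 4 without animal 504 and 3 without 505 or without libraries with another tissue's markers. Targets of CAR and PXR rose with 1 of 25 higher (5 adjusted over the list alone; adjusted p = 0.00259 with an estimated correlation), NRF2 targets with 1 of 23 (adjusted p = 0.0457 with an estimated correlation) and clock genes with 1 of 6 (adjusted p = 0.0297 with an estimated correlation). Pancreas acinar markers rose with 1 of 6 higher (5 adjusted over the list alone; adjusted p = 0.00296, and adjusted p = 0.103 with an estimated correlation). The heat shock, mitochondrial, fatty acid, adipocyte, ER stress, and oviduct and ciliated cell lists also passed camera, none with an estimated correlation (adjusted p = 0.074, adjusted p = 0.163, adjusted p = 0.43, adjusted p = 0.496, adjusted p = 0.525 and adjusted p = 0.525).

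Lower concentrations moved few probes in ovary. At 10 ppm 1,2-DCB Dbp rose by 1.07 ± 0.22 (n = 10 and 5, adjusted p = 0.0135) as 1 of 2 calls; its adjusted p was 0.0828 without animal 203, 0.0531 without animal 205 and 0.929 with the covariate. The count ranged from 0 to 18 when 1 library was left out. At 100 ppm 2 probes passed, and from 0 to 7 when 1 library was left out. At 1 and 30 ppm edgeR called 0, with 4.24% and 19.6% at an unadjusted p under 0.05 and 0 and 32 by DESeq2; the 30 ppm count was up to 22 when 1 library was left out. Under 1,4-DCB edgeR called 0 at 1, 10 and 50 ppm, with 3.94%, 2.65% and 6.60% at an unadjusted p under 0.05 and 0, 0 and 1 by DESeq2; without control 10 the 10 ppm count was 4. At 150 ppm 1 probe passed, and from 0 to 2 when 1 library was left out.

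The isomers were compared at the concentrations they share. At 1 ppm edgeR called 0 differences in any tissue, with 2.0% of probes at an unadjusted p under 0.05 in liver, 10.04% in kidney, 4.32% in lung, 3.38% in heart and 3.54% in ovary, and 0 by DESeq2 in each. With all libraries 5.6% of probes differed in liver, 25 probes in lung and 4 in kidney. The 95% interval of the difference, 1,4-DCB minus 1,2-DCB, was -1.09 to 1.28 for Gsta1 and -1.03 to 0.64 for Cyp2b10 in liver. Over all probes the median distance from its middle to its end was 0.63 log2 units in liver, 0.49 in kidney, 0.42 in lung, 0.44 in heart and 0.45 in ovary. The whole interval lay within 1 log2 unit of 0 in 59.2% of the liver probes and 73% of the lung probes.

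At 10 ppm the isomers differed in liver at 41 probes, 21 higher with 1,4-DCB and 20 lower. The difference in Cdkn1a was 3.95 ± 0.62 (n = 9 and 4 for 1,2-DCB, 7 and 4 for 1,4-DCB, adjusted p = 5.97e-05), 4.58 without 1,2-DCB animal 202 and 2.54 with the Dbp covariate. In Por it was -1.26 ± 0.20 and in Hlf -2.64 ± 0.54, the latter ended by all libraries (-2.66, adjusted p = 0.0652) and by the covariate (-1.16, adjusted p = 0.43). CAR and PXR targets lower with 1,4-DCB numbered 4, and 11 adjusted over the list alone. Gsta1 and Cyp2b10 did not differ past the test, with -0.81 (95% interval -1.84 to 0.23) and -0.50 (-1.24 to 0.24). The count was 7 with all libraries or with the covariate, 62 by DESeq2 and 27 without 1,2-DCB animal 201 or 1,4-DCB animal 203. In heart 28 probes differed, 21 higher with 1,4-DCB and 7 lower, among them Dbp by -2.41 (95% interval -3.43 to -1.39) and Cdkn1a by 1.70 ± 0.35. The covariate ended both calls, at -0.60 (adjusted p = 0.413) and 0.69 (adjusted p = 0.656). The heart count ranged from 13 to 35 when 1 library was left out. In lung 10 differed, 3 higher with 1,4-DCB and 7 lower, among them Adm by 1.63 ± 0.32 and Hlf by -1.97 ± 0.37. With the covariate these values became 0.54 (adjusted p = 0.89) and -0.68 (adjusted p = 0.767). Nqo1 in lung differed by -0.50 (-0.91 to -0.10, adjusted p = 0.469).

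In kidney 6 probes differed between the isomers at 10 ppm, 4 higher with 1,4-DCB and 2 lower, but 0 by edgeR with all libraries, and from 0 to 18 when 1 library was left out. In ovary edgeR called 0 differences, with 234 probes at an unadjusted p under 0.05 and 1 by DESeq2. The ovary count ranged from 0 to 7 when 1 library was left out. Dbp in ovary differed by -1.20 (95% interval -1.84 to -0.56, adjusted p = 0.145).

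The highest concentrations of the isomers differ, 400 ppm for 1,4-DCB and 250 ppm for 1,2-DCB, and their changes are set side by side here. In liver Cyp2b10 rose by 4.29 with 1,4-DCB and by 1.85 with 1,2-DCB, a difference of 2.44 (95% interval 1.76 to 3.12, adjusted p = 1.49e-07). Cyp3a11 differed by 1.39 (1.06 to 1.72), and Cyp2c54 by 2.76 ± 0.20. Afp differed by -5.18 ± 0.54, S100a6 by -4.40 ± 0.43 and Mup19 by 4.16 ± 0.27, and Ces2a by 2.17 ± 0.14. Cyp2e1 differed by 1.14 (0.73 to 1.55), ended by all libraries (0.73, adjusted p = 0.336). Gsta1 did not differ past the test, by 0.16 (-0.78 to 1.09), and turned negative with all libraries (-2.16, adjusted p = 0.317) and without 1,4-DCB control 2 (-0.00). By list, CAR and PXR targets were higher with 1,4-DCB at 13 probes and lower at 1, PPARA targets higher at 11, fatty acid genes higher at 6, cell cycle genes lower at 12 and extracellular matrix genes lower at 8. Cell type markers moved too, with hepatocyte markers higher at 4 of 12, red cell markers at 5 of 5 and macrophage markers lower at 3 of 5. In all, 447 probes differed, 238 higher with 1,4-DCB and 209 lower; 182 did with all libraries and 206 with number blocks. At 150 ppm 1,4-DCB against 250 ppm 1,2-DCB 673 differed in liver, 311 higher and 362 lower, and 431 did with all libraries.

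In lung 228 probes, 8.3% of those tested, differed at the highest concentrations, 33.3% of them higher with 1,4-DCB; 4.7% did with all libraries and 4.4% with number blocks. Gsta1 differed by -4.43 (95% interval -5.15 to -3.71, adjusted p = 2.46e-15), Nqo1 by -1.84 (-2.24 to -1.45), Cbr3 by -1.37 ± 0.16 and Gsr by -0.75 ± 0.09, and Itgae by 1.34 ± 0.21. NRF2 targets were lower with 1,4-DCB at 15 probes and higher at 0, cell cycle genes lower at 32 of 58, and heat shock genes higher at 7. At 150 against 250 ppm 343 lung probes differed, 34.7% of them higher, or 179 with all libraries and 208 without 1,2-DCB animal 506R. In heart 33 probes differed at the highest concentrations, 24 higher with 1,4-DCB and 9 lower, among them H2-aa by 2.08 ± 0.40, Cd74 by 1.76 ± 0.36 and Lcn2 by -1.77 ± 0.34. The count ranged from 14 to 94 when 1 library was left out, and was 14 with number blocks.

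In kidney 23 probes differed at the highest concentrations, 7 higher with 1,4-DCB and 16 lower. Insig1 differed by -1.66 ± 0.24 and Cbr3 by -1.27 ± 0.20, while Slc22a7, by 1.26 ± 0.23, was ended by number blocks (0.90, adjusted p = 0.0845). Cholesterol synthesis genes were lower with 1,4-DCB at 6 probes, and at 13 with 1 higher adjusted over the list alone. Gsta1 did not differ past the test, by -0.92 (95% interval -1.60 to -0.24, adjusted p = 0.263). The count ranged from 12 to 72 when 1 library was left out. In ovary Mup19 differed by 4.33 ± 0.86 (adjusted p = 0.011), ended by number blocks (3.83, adjusted p = 0.0505) and at 3.66 without 1,2-DCB control 4, and Hsph1 by 0.67 ± 0.15, ended without 1,4-DCB animal 501 (0.63, adjusted p = 0.0558).

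Probes changed by each compound at its highest concentration were compared, with separate controls. Dbp was above control with both, so overlap need not reflect exposure. In liver 367 rose with both against 117.7 expected under independence, and 243 fell against 87.4. Another 13 rose with 1,2-DCB but fell with 1,4-DCB, and 20 did the reverse. In lung 37 rose with both against 7.73 and 23 fell with both against 4.21. In kidney 14 rose with both against 1.15 and 7 fell against 0.544. In heart 30 rose against 8.84 and 26 fell against 4.86, and in ovary 1 rose against 0.822 and 0 fell against 0.231.

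Control animals of the compounds were compared to see how far the series differed without exposure. In ovary 167 probes differed, 47 higher in the 1,4-DCB controls and 120 lower, among them the steroidogenic gene Star by -3.55 ± 0.60, S100a4 by -3.66 ± 0.59 and S100a6 by -1.98 ± 0.31 (n = 10 and 10). Adrenal markers were lower at 3 of 10 probes, macrophage markers at 2 of 5, and oocyte markers higher at 1 of 7 (5 adjusted over the list alone). The ovary count ranged from 84 to 234 when 1 library was left out. In heart 46 differed, 25 higher and 21 lower, among them Decr1 by 0.67 ± 0.12 and Gbp6 by -1.0 ± 0.19. The heart count ranged from 17 to 67 when 1 library was left out. In liver 15 differed, 7 higher and 8 lower, among them Bex4 by 1.07 ± 0.15 and Sult3a1 by -3.37 ± 0.61, both ended by all libraries (1.11, adjusted p = 0.144, and -2.37, adjusted p = 0.14). The liver count was 9 without 1,4-DCB control 10 and 1 with all libraries. In kidney Fgf1 differed by -0.68 ± 0.10 (adjusted p = 0.000159) and in lung Slc6a20a by -1.07 ± 0.19 (adjusted p = 0.000994).

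Other tissues were compared with liver by the difference of changes at the highest concentration. Tissues of an animal were not paired in this fit. Under 1,2-DCB, Afp rose by 7.94 in liver, and its change was 0.03 in kidney and 1.35 in lung. Egfr changed by -2.85 in liver, -0.03 in kidney and -0.02 in ovary, and Ces1g by 0.25 in liver and 3.40 in lung. Lgals1 changed by 3.70 in liver, 0.27 in heart and -0.16 in ovary, and Gins2 by 4.28 in liver and 0.24 in heart. Under 1,4-DCB, Gsta1 rose by 7.38 in liver with 0.92 in lung, Cyp2b10 by 4.29 with 0.08 in lung and Cbr3 by 4.47 with 0.03 in kidney. Abcc4 changed by 4.94 in liver and -0.07 in heart, Rrm2 by 3.21 in liver and -0.13 in ovary, and Nol3 by 2.77 in liver and -0.11 in heart. Each of these differences passed its own test. Under 1,2-DCB cell cycle genes were lower than in liver at 47 probes in lung and 50 each in kidney, heart and ovary.

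The share of probes called higher than in liver depended on the scaling, so directions over all probes are not stated. For lung under 1,2-DCB it was 65.5%, 49.8% with RLE size factors and 37.4% with the attenuation factors undone, which moved the median of all probes by -0.14 and -0.23. Under 1,4-DCB it was 68.4% in lung and 50.2% with RLE, and 52.2% in kidney and 32.4% with RLE.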

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

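The tests of library spacing in kidney and of the Dbp level, the covariate and the interval of the hepatocyte difference were chosen after the results were seen. The marker threshold for leaving libraries out was also set after seeing the data, though before the counts without them were known.

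A sample far from the others was sought in 208 groups of animals by its gap to the nearest animal over the range of the group, and 26 groups had one; chance picks about 1 in 20 groups. In liver at 250 ppm 1,2-DCB, animal 506R stood apart in Rrm1 (ratio 0.767), Rrm2 (0.75) and Slc1a2 (0.632), with Rrm2 at 200 CPM against a median of 90.2 CPM in the others. Animal 501 of that group did so in Cyp1a1 (0.689), and liver 1,4-DCB control 7 in Gstm3 (0.57). In lung at 400 ppm 1,4-DCB it was animal 502 in Slc7a11 (0.745). Heart 1,2-DCB control 4 stood apart in H2-aa (0.832), Cd74 (0.821), Ccl7 (0.789) and Ccl2 (0.553), with H2-aa at 204 CPM against 34 CPM. Heart animal 504 at 250 ppm 1,2-DCB was low in Mt1 (0.683), heart 1,4-DCB control 2 was high in Hp (0.661), and animal 502 at 400 ppm 1,4-DCB in Lcn2 (0.79). In ovary 1,2-DCB controls it was control 4 in Chil3 (0.689) and Mup19 (0.548), control 9 in Mmp12 (0.473) and control 2 in Melk (0.571). At 250 ppm 1,2-DCB it was ovary animal 508 in Hba-a1 (0.789) and Hmmr (0.707) and animal 503 in Mup19 (0.582). At 400 ppm 1,4-DCB it was ovary animal 504 in Fabp2 (0.976) and animal 505 in Ctrb1 (0.955). Heart animal 501 at that concentration stood apart in Cyp2f2 (0.999), Acly (0.905) and Hp (0.835). In the Dbp level per animal it was animal 302 at 30 ppm 1,2-DCB (0.731).

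A difference between groups was tested for each other tissue against liver. At 250 ppm 1,2-DCB, 833 probes changed differently in kidney and 967 in lung (705 and 841 with animals as blocks). The counts were 707 in heart (622) and 931 in ovary (851). At 400 ppm 1,4-DCB they were 506 in kidney (346), or 336 without animal 502, and 823 in lung (742). They were 762 in heart (560) and 576 in ovary (429). Among named genes under 1,2-DCB, other tissue minus liver, Afp differed by -7.90 in kidney and -6.37 in lung, Egfr by 2.83 in kidney, and Ces1g by 3.35 in lung. Gins2 differed by -4.07 and Lgals1 by -3.46 in heart, and Lgals1 by -3.71 and Egfr by 2.98 in ovary. Under 1,4-DCB, Cbr3 differed by -4.31 and Glul by 1.71 in kidney, Gsta1 by -6.26 and Cyp2b10 by -4.03 in lung, Abcc4 by -5.00 and Nol3 by -2.90 in heart, and Rrm2 by -3.29 and Hgf by 1.60 in ovary. In these 8 comparisons no other of 40 splits of the animals called as many probes, the highest being 450, in ovary under 1,2-DCB.

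A signal in libraries left out of the comparisons came from the 16 kidney libraries labelled for potential tissue contamination. The pancreatic amylase gene Amy2a4 had a median of 480 CPM in them and 1.59 CPM in the kidney libraries used, and the pancreatic protease gene Ctrb1 31.3 against 0.0809 CPM. Among other kidney libraries left out, 1,2-DCB control 5 held 337500 CPM of Amy2a4, and animal 302 at 30 ppm 1,2-DCB held the liver gene Apoa1 at 19520 CPM. Pancreas collected with kidneys at random over the library numbers is argued against by the spacing of the 16 numbers, with 10 gaps of 4 or 5 between neighbours (permutation p = 0.00078, over all windows of 1 to 3 gap sizes). For the liver transcripts, carry-over from the library of animal 302 to those in the same row or column of a plate may be a source. In 19 such libraries 9 hepatocyte probes were higher by a median of 0.456 log2 units than in 52 others (95% interval 0.213 to 0.601, one-sided permutation p = 0.00112). The difference predicted for carry-over was over 1 and that against it under 0.5, a bound inside the interval. The layout was read from the spacing of the labelled libraries, so carry-over and other sources cannot be told apart.

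RNA of other tissues in a few heart libraries may account for the 668 probes called at 150 ppm 1,4-DCB, since 1.2% as many were called without libraries with another tissue's markers. Animal 405 held Fabp4, Cyp2e1 and Adipoq at 1374, 583 and 18.6 CPM, with heart medians of 260, 8.80 and 0.122 CPM. Animal 403 held Cyp2f2 at 187 CPM. At 400 ppm 318 probes were called, and 46.9% as many without all such heart libraries, between the bounds set beforehand. The count was 87 without animal 501, the only one of that group past the threshold. Without animal 503, with adipocyte markers 1.67 above the median, it was 120. RNA of other tissues cannot be told apart from an effect of exposure here. Fat or lung taken with the heart is a candidate source, and a change within the heart stays open for the rest. Of 40 splits only the real one gave as many calls, with highest others of 561 at 150 ppm and 100 at 400 ppm. A drawn split can differ from the real one by few animals, so a high count below the real one decides nothing here.

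The Dbp level of an animal over its tissues was higher than in controls in every 1,2-DCB group from 10 ppm up, with means of 1.64 ± 0.25 at 10 ppm, 1.08 ± 0.50 at 250 ppm and -0.80 ± 0.87 in controls (SD, log2). Dbp fell from 10 to 250 ppm (Spearman rho -0.509, two-sided permutation p = 0.0172). At 250 ppm against the highest lower group, rechosen in each resample, the one-sided permutation p was 0.0623. Groups may differ in collection time, so an effect rising with concentration is undecided. In the 1,4-DCB series the means were -0.65 ± 0.87 in controls and -1.49, -0.92, -0.47, -0.18 and 1.15 at 1, 10, 50, 150 and 400 ppm, so they rose from 1 ppm up but passed the control mean only from 50 ppm. An order of collection that the animal numbers follow may be a source, since within groups Dbp moved with the animal number (mean Spearman rho 0.498, above 0 in 11 of 12 groups, two-sided permutation p = 2e-04). Times of collection were not used here, and an effect of exposure on the clock stays open in both series. With the Dbp covariate, the 10 ppm 1,2-DCB share of probes called went from 5.34% to 2.08% in liver and from 0.978% to 0.244% in heart.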

How the results depend on the processing

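The Dbp covariate and the other-tissue marker fit were chosen after the results were seen. RLE size factors moved 0 counts past 1.5 times in either direction, no filter 1 and the attenuation factors undone 1, whereas the libraries used, the tool and the covariate moved more. The counts at 250 ppm 1,2-DCB in liver, lung and heart stayed within 1.5 times under every alternative run. Percentages below are of the probes tested, isomers at 400 and 150 ppm are 1,4-DCB against 1,2-DCB at 250 ppm, and a replicate block by number could not be fitted for isomers at 150 ppm. The cause of the changes was not tested.

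Using all libraries gave percentages in liver 12, 1.0, 4.2 and 9.5 at 1, 10, 30 and 100 ppm 1,2-DCB, 0.080 and 20.4 at 50 and 400 ppm 1,4-DCB, 5.6 and 0.28 for isomers at 1 and 10 ppm, 7.2 and 17 for isomers at 400 and 150 ppm and 0.040 for controls. In kidney it gave 0.15, 10.4 and 8.7 at 1, 30 and 100 ppm 1,2-DCB, 0.037 at 1 ppm 1,4-DCB and 0.15 and 0 for isomers at 1 and 10 ppm. In lung it gave 19.7 and 1.2 at 1 and 10 ppm 1,2-DCB, 0.036, 0.55 and 1.6 at 10, 50 and 400 ppm 1,4-DCB, 0.91 for isomers at 1 ppm, 4.7 and 6.5 for isomers at 400 and 150 ppm, 0.18 for controls and 19 at 400 ppm 1,4-DCB against liver. Using the same compound only gave percentages in liver 3.2 at 10 ppm 1,2-DCB and 0.24 at 50 ppm 1,4-DCB. In kidney it gave 0.87, 1.8 and 0.075 at 10, 30 and 100 ppm 1,2-DCB and 0.075 and 0.64 at 1 and 400 ppm 1,4-DCB. In lung it gave 1.0, 3.0 and 3.8 at 10, 30 and 100 ppm 1,2-DCB and 0.29, 2.2, 0.73 and 5.1 at 10, 50, 150 and 400 ppm 1,4-DCB. In heart it gave 1.2 and 0.47 at 30 and 100 ppm 1,2-DCB. In ovary it gave 0.27, 0.42 and 0 at 10, 30 and 100 ppm 1,2-DCB and 0 at 150 ppm 1,4-DCB. The Dbp covariate gave percentages in liver 2.1 and 6.8 at 10 and 30 ppm 1,2-DCB, 2.5 at 50 ppm 1,4-DCB and 0.27 for isomers at 10 ppm. In kidney it gave 0.22, 0.37 and 6.6 at 10, 100 and 250 ppm 1,2-DCB, 0.18 and 0.22 at 1 and 400 ppm 1,4-DCB, 5.1 for isomers at 150 ppm and 2.0 for controls. In lung it gave 0.83 and 2.6 at 10 and 30 ppm 1,2-DCB and 0 for isomers at 10 ppm. In heart it gave 0.24 and 0.29 at 10 and 30 ppm 1,2-DCB, 19.6 at 400 ppm 1,4-DCB, 0 for isomers at 10 ppm and 5.1 for isomers at 150 ppm. In ovary it gave 0.11, 0.037 and 8.1 at 30, 100 and 250 ppm 1,2-DCB. DESeq2 gave percentages in liver 1.6 at 50 ppm 1,4-DCB, 2.4 for isomers at 10 ppm and 1.1 for controls. In kidney it gave 0.84 and 1.4 at 10 and 30 ppm 1,2-DCB, 1.8, 0.073, 0.26 and 0.11 at 1, 10, 50 and 150 ppm 1,4-DCB, 0.77 for isomers at 10 ppm, 1.8 for isomers at 400 ppm and 2.2 for controls. In lung it gave 0.87 at 1 ppm 1,2-DCB, 0.036 at 1 ppm 1,4-DCB and 1.1 for controls. In heart it gave 3.4 for controls. In ovary it gave 1.2, 1.2 and 0.74 at 10, 30 and 100 ppm 1,2-DCB, 0.037 at 50 ppm 1,4-DCB, 0.037 for isomers at 10 ppm and 2.9 and 1.3 for isomers at 400 and 150 ppm. A replicate block gave 7.9%, 4.4%, 0.57% and 0.37% for isomers at 400 ppm in liver, lung, heart and ovary, and 0.11% for lung controls. Leaving out libraries with another tissue's markers gave percentages in kidney 0.18 and 0.073 at 1 and 50 ppm 1,4-DCB, 0.51 for isomers at 400 ppm and 1.4 for controls. In heart it gave 0.32 and 6.0 at 150 and 400 ppm 1,4-DCB, 0.45 for isomers at 10 ppm and 0.53 and 3.2 for isomers at 400 and 150 ppm. In ovary it gave 0.037 at 100 ppm 1,2-DCB, 0.11 at 400 ppm 1,4-DCB, 0.037 for isomers at 10 ppm and 0.70 and 1.6 for isomers at 400 and 150 ppm. With no filter, ovary at 100 ppm 1,2-DCB gave 0%, and with the attenuation factors undone ovary isomers at 150 ppm gave 0.59%, of which 68.8% were higher, against 83.3% before. With an estimated correlation, lists called fell under 1,2-DCB to 1 from 8 in liver, 3 from 13 in kidney, 1 from 8 in lung, 1 from 7 in heart and 0 from 9 in ovary, and under 1,4-DCB to 3 from 8, 3 from 7, 2 from 6, 1 from 9 and 3 from 10 in the same order. Gsta1 in liver turned to -0.043 at 50 ppm 1,4-DCB and to -2.16 for isomers at 400 ppm with all libraries.

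Leaving out each library in turn gave percentages in liver 2.6 to 6.0 at 10 ppm 1,2-DCB, 0.12 to 2.2 and 3.6 to 6.0 at 50 and 150 ppm 1,4-DCB, 1.0 to 2.0 for isomers at 10 ppm and 0.35 to 0.81 for controls. In kidney it gave 0.18 to 0.40, 0.29 to 0.70 and 0 to 0.037 at 10, 30 and 100 ppm 1,2-DCB, 0.073 to 2.1, 0 to 0.073, 0 to 0.073 and 0.51 to 1.2 at 1, 50, 150 and 400 ppm 1,4-DCB, 0 to 0.66 for isomers at 10 ppm, 0.44 to 2.6 for isomers at 400 ppm, 0.037 to 1.9 for controls and 12 to 19 at 400 ppm 1,4-DCB against liver. In lung it gave 0 to 3.8, 0.83 to 2.2 and 3.8 to 7.3 at 1, 10 and 100 ppm 1,2-DCB, 0 to 0.036, 0.036 to 0.073, 0.44 to 1.4 and 1.5 to 2.9 at 1, 10, 50 and 400 ppm 1,4-DCB, 7.6 to 14 for isomers at 150 ppm and 0.036 to 0.94 for controls. In heart it gave 0.48 to 1.3, 0.97 to 2.5 and 0.28 to 0.86 at 10, 30 and 100 ppm 1,2-DCB, 0 to 0.040, 1.8 to 34 and 3.5 to 17 at 10, 150 and 400 ppm 1,4-DCB, 0.52 to 1.4 for isomers at 10 ppm, 0.56 to 3.8 and 3.0 to 20.2 for isomers at 400 and 150 ppm and 0.69 to 2.7 for controls. In ovary it gave 0 to 0.66, 0 to 0.81 and 0 to 0.26 at 10, 30 and 100 ppm 1,2-DCB, 0 to 0.15, 0 to 0.073 and 0.11 to 0.62 at 10, 150 and 400 ppm 1,4-DCB, 0 to 0.26 for isomers at 10 ppm, 0.29 to 2.8 and 0.037 to 2.5 for isomers at 400 and 150 ppm and 3.1 to 8.6 for controls. Gsta1 for liver isomers at 400 ppm ranged from -0.00046 to 0.54. Of probes changed differently from liver, the share higher moved under 1,2-DCB from 38.1% to 52.4% in heart with RLE and from 52.1% to 35.7% in ovary with the attenuation factors undone, and under 1,4-DCB from 49.2% to 60.7% in heart with the latter.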

Other observations

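The splits were planned, and the observations on gene groups below were chosen after the results were seen. In liver at 100 ppm 1,2-DCB, heat shock genes were lower at 9 probes and higher at 0, and ER stress genes lower at 10 and higher at 2. Cholesterol synthesis genes were higher at 8 and lower at 0. Interferon genes were lower at 5, 12 and 6 probes at 10, 30 and 100 ppm, with 0 higher at each. Between the isomers at their highest concentrations, heat shock genes were higher with 1,4-DCB than with 1,2-DCB at 5 of 18 probes in liver, 7 in lung, 3 in heart, 2 in ovary and 0 in kidney, and lower at 0. These are counts of probes past edgeR, with no list test at these contrasts.

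Other splits of the same animals into groups of the same sizes were counted in each contrast with at least 3 animals per group, 40 drawn splits in each and all 56 for kidney at 30 ppm 1,2-DCB. The real split alone gave as many calls in liver at every concentration that called probes, with highest other counts of 69, 74, 179 and 996 under 1,2-DCB from 10 ppm up and 19, 59 and 513 under 1,4-DCB from 50 ppm up. It held in kidney for 10, 30 and 250 ppm 1,2-DCB, with highest others of 0, 1 and 32, and in lung for 10, 30, 100 and 250 ppm 1,2-DCB, with 10 at 10 ppm, 12 at 30 ppm and 464 at 250 ppm. In lung under 1,4-DCB it held from 10 ppm up, with 1, 2, 3 and 28, in heart at 30, 100 and 250 ppm 1,2-DCB, with 4, 9 and 13, and in ovary at 250 ppm 1,2-DCB, with 39. It held for the isomer differences with calls in liver and lung, for heart at 10 ppm and at 150 against 250 ppm, for ovary at the highest concentrations, and for the controls of every tissue but kidney.

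Chance was not excluded for kidney at 1 ppm 1,4-DCB, where 18 of 40 splits, the real one counted here and below, called as many as the real 13 and the highest called 422, or at 400 ppm, where 13 splits reached 28 and the highest called 195. It was not for the kidney isomer differences of 6, 23 and 80 probes, each reached by 2 splits including the real one, with a highest other of 167 for the 23 and 92 for the 80, or for the kidney controls, where 5 splits reached 24 and the highest called 71. Counts several times the real ones, as for all of these but the 80, point to a structure of the kidney samples that the groups do not follow. In heart 2 splits reached the 24 of 10 ppm 1,2-DCB (highest 52) and 4 the 33 of the isomers at their highest concentrations (highest 66). In ovary 16 splits reached the 2 of 10 and of 100 ppm 1,2-DCB (highest 28 and 45), 23 the 1 of 150 ppm 1,4-DCB (highest 5), 2 the 13 of 400 ppm (highest 13) and 3 the 6 of 150 against 250 ppm (highest 49), and those several times the real count point to a structure here as well. For contrasts with 0 calls by edgeR the splits decide nothing, since all 40 give at least 0, and the highest called 180, in kidney at 50 ppm 1,4-DCB.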
